A study of Mus musculus with 7 samples.

How the data were processed

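The knockdown was measured by RNA sequencing of 4 libraries from proliferating C2C12 cells, and the pull-down by sequencing of RNA recovered with lnc-31 or lacZ probes, per the labels. The siRNA libraries were made with a stranded mRNA kit and the pull-down libraries with a whole-transcriptome amplification kit, per the labels' protocols. The authors deposited FPKM values for the knockdown, made with CASAVA, Trimmomatic, Bowtie2, BWA, TopHat2 and Cuffdiff on build mm10, per the submitters' processing notes, which give neither order nor versions. The pull-down files used CASAVA, Trimmomatic, cutadapt, Bowtie2, TopHat2 and Picard on mm10, per the same notes. The peak caller is not given in the sources used here. Column 7 of the deposited peak lists was read as a p-value because its values lie above 0 and up to 0.01 in both lists. No label or header names it, so each p printed for a peak rests on that reading. The lists come with an empty score and 1 strand symbol throughout, so strand carried no information. Peaks were whole numbers of 200-base windows. The input library was not analysed here.

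FPKM is not a count, and low values showed no steps from which reads could be recovered, so depth is unknown and no counting interval is given. The table lists rows whose highest value is at least 0.307 FPKM. Sums of FPKM ranged from 1515596 to 2466046 per library, because rows over 10000 FPKM took 61.9% to 76.0% of them. An exact 0 stood in 132 rows, 34 of them tested, and can be a failed estimate. The mitochondrial row mt-Nd2 was at 395110 FPKM in scrambled siRNA 2 and at 2876 to 3401 in the other libraries. Row names that merge several genes were kept as deposited. There were 0 sample columns that matched no label.

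Rows with a mean of 1 FPKM or more (11500) were transformed to log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3, with a trended prior variance (prior degrees of freedom 3.62), two-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2(FPKM + 1) scale, which understates the change of low genes. The 23 gene lists and the main tests of genes, lists and peaks were fixed before the data were examined, while the tests of explanations, of clock genes and of matched random lists were chosen after results were seen, and 1 list and 1 gene with many peaks are not reported here. Lists with 5 or more tested members were tested with limma's camera (preset correlation 0.01), and with an estimated correlation and fry beside it. None of the 9 camera calls held with the estimated correlation. That version estimates the correlation from 4 libraries, and its smallest unadjusted camera p for any list was 0.089 (G2/M and mitosis). It could hardly call a list in this design, so its p-values do not settle whether the preset calls hold. For the 9 called lists the estimated correlations ran from 0.11 (p53 targets) to 0.58 (ribosomal proteins), against the preset 0.01. If genes of a list vary together that strongly, the preset camera p-values are too small. Fry did not call ribosomal proteins (adjusted p = 0.33), p53 targets (0.17) or fibroblast markers (0.17). The fit was tested on simulated data for the knockdown comparison (11500 genes, 200 changed). It recovered 67.2% of 1.5-fold, 95.5% of 2-fold and 100% of 3-fold changes, and 4.37% of its calls were false. Changes were planted only in genes with a mean log2(FPKM + 1) above 2, and none was below 1.5-fold. Each gene was drawn independently, so variation shared between genes was left out. The rate of false calls may therefore not carry over to the real libraries. Of the 1429 genes called in the real data, 169 reached 1.5-fold, so these rates do not cover most of those calls.

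Genes were named by a rule: the 10 highest and 10 lowest log2 fold changes among called genes whose groups did not overlap, leaving out names that begin Gm or end Rik, up to 4 members of each list by smallest p, the row that names Mir31, Rock1 and Ybx1. In the pull-down these were the 10 widest peaks without lacZ overlap (the score being empty), the 10 genes with most such peaks, the 5 widest lacZ peaks, and peaks in Rock1, Ybx1 and the lnc-31 locus. Rock2, Mtap, the clock genes, called peak genes and the lowest p per list were chosen after their values were seen.

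Peak lists were compared with bedtools 2.31.1 with a minimum overlap of 1 base. Genes came from RefSeq on GRCm38.p6, which shares coordinates with mm10. Of 13376 table rows, 12676 (94.8%) matched a RefSeq gene. The reference gave gene spans without exons, so the planned exon overlap was replaced by overlap with the gene body. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. The alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean of 5 FPKM, quantile normalization, median of ratios scaling, a constant prior variance, the replicate number as a block, each library left out in turn, a 1.5-fold threshold, other overlap rules, and subsets of peaks. When 1 library is left out, the lone library is assumed to vary like the other group.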

Results

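The series measured RNA in C2C12 cells, a mouse myoblast line that grows as proliferating precursors and can be switched to muscle differentiation. The first experiment was a knockdown in proliferating cells, with 2 libraries labelled scrambled siRNA and 2 labelled lnc-31 siRNA, given as FPKM (fragment counts scaled to transcript length and to the mapped fragments of the library) for 13376 rows. The second was a pull-down, in which biotinylated antisense probes against the long noncoding RNA lnc-31, or against the bacterial lacZ sequence as background, recovered RNA that was then sequenced. It had 1 library per probe set, given as peak lists, and 1 input library that was not analysed here. The number of reads per library is unknown from these files, so the precision of the knockdown comes only from the spread between libraries. Spearman's correlation across rows was 0.993 between the scrambled siRNA libraries and 0.990 between those labelled lnc-31 siRNA, and Pearson's on the log2 scale was 0.968 and 0.951. The first principal component, with 41.4% of the variance, set lnc-31 siRNA 1 (score 39.1) apart from lnc-31 siRNA 2 (-10.4) and the scrambled siRNA libraries (-12.4 and -16.3). Counts with each library left out are given for most lists below. The labels do not say that libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

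The title of the series concerns lnc-31 and the translation of Rock1 mRNA, and the knockdown comparison begins with these RNAs. The table has no row named lnc-31. The row that names Mir31, the microRNA whose host transcript lies at this locus, also carries an assembled transcript identifier (Mir31,XLOC_026180). It stood at 14.5 ± 1.58 FPKM with scrambled siRNA and 13.1 ± 1.40 in the libraries labelled lnc-31 siRNA (SD, n = 2 each), a log2 fold change of -0.14 (limma, SE 0.099, adjusted p = 0.38). A fall of the targeted RNA was therefore not shown by this row, and every direction below is that of libraries labelled lnc-31 siRNA. Rock1, a serine/threonine kinase, was at 16.8 ± 0.357 and 17.7 ± 0.115 FPKM (log2 fold change 0.07, adjusted p = 0.38). Ybx1, which encodes the RNA-binding protein YB-1, was at 519 ± 7.05 and 504 ± 7.75 FPKM (log2 fold change -0.04, adjusted p = 0.56). Neither difference passed the test. Among 6 other tested genes within 1 Mb of Mir31, Mtap fell from 125 ± 1.86 to 88.2 ± 0.583 FPKM (log2 fold change -0.50, adjusted p = 0.0056). Mtap encodes an enzyme of methionine salvage and lies 226.7 kb from Mir31. Gm12602, 189.2 kb from Mir31, had a log2 fold change of -0.19 (adjusted p = 0.065), and Klhl9, Focad, Mllt3 and Mrpl48-ps did not pass either.

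**Figure D1:**
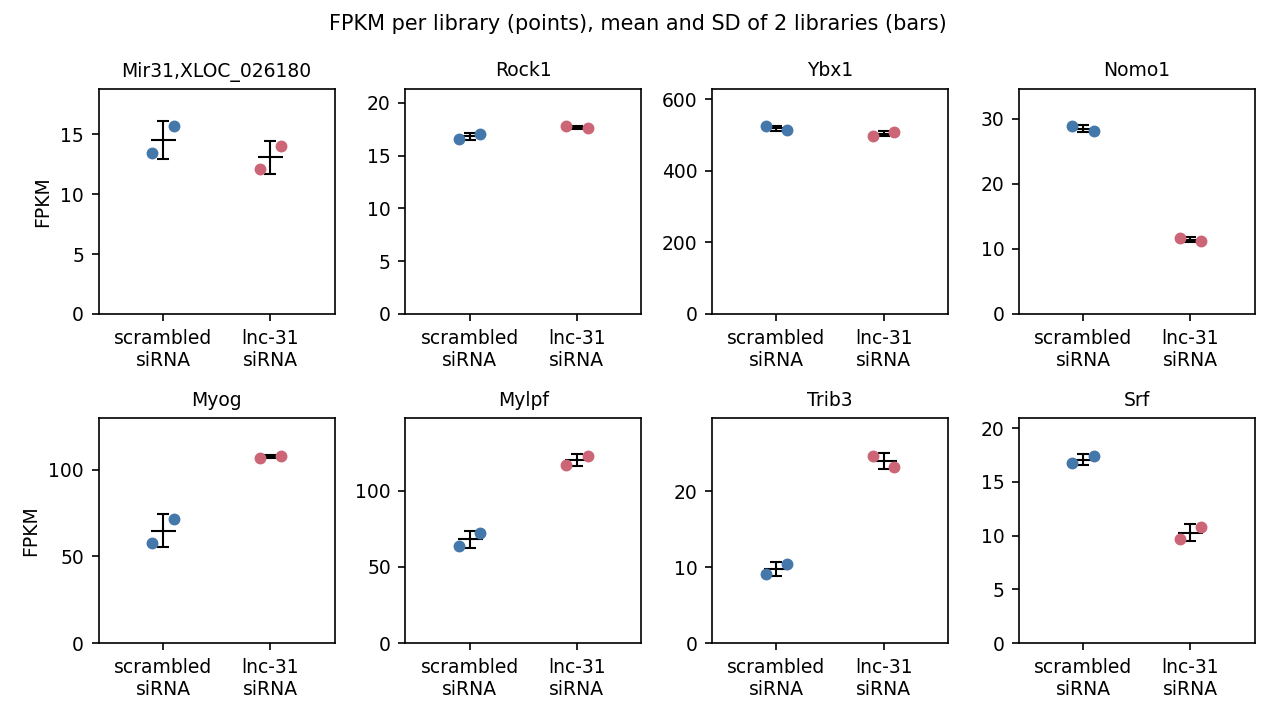
FPKM of 8 rows in the scrambled siRNA and lnc-31 siRNA libraries, with each library as a point and the mean ± SD of 2 libraries as a bar on axes that start at 0. The groups lie close together for the row that names Mir31, Rock1 and Ybx1, while Nomo1 and Srf are lower and Myog, Mylpf and Trib3 higher in the lnc-31 siRNA libraries.

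Muscle genes were higher in the libraries labelled lnc-31 siRNA. Of 38 tested contractile and differentiation genes, 31 rose and none fell, and their median log2 fold change was 0.64. The embryonic myosin heavy chain Myh3 rose from 5.08 ± 0.253 to 10.02 ± 0.0605 FPKM, cardiac actin Actc1 from 42.0 ± 0.669 to 70.4 ± 0.406 and the fast light chain Mylpf from 68.0 ± 5.63 to 119.9 ± 4.10. Myoglobin (Mb) rose from 4.30 ± 0.332 to 10.5 ± 0.274 FPKM, and Myl1 from 18.3 ± 2.04 to 38.3 ± 2.72. Camera, which compares a list with all other genes, gave the list an adjusted p of 4.65e-22 with its preset correlation. With an estimated correlation it gave adjusted p = 0.44. With 4 libraries the estimated version had little power, for this list and for those below. The estimated correlation of this list was 0.38 against the preset 0.01, so the preset p may be far too small. Adjusted over the list alone, 34 rose. With scrambled siRNA 1, scrambled siRNA 2, lnc-31 siRNA 1 or lnc-31 siRNA 2 left out, 21, 24, 20 and 20 members rose.

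Of 13 tested myogenic regulators, 3 rose and 2 fell. Myog, the transcription factor of early differentiation, rose from 64.8 ± 9.64 to 107.5 ± 0.874 FPKM (log2 fold change 0.73, adjusted p = 0.013). Myod1, the factor that specifies muscle, rose by 0.36 on the log2 scale and Mef2a by 0.35, and Mef2d fell by 0.26. The calls of Myod1, Mef2a and Mef2d were lost without scrambled siRNA 1 (adjusted p = 0.096, 0.10 and 0.12), without scrambled siRNA 2 (0.075, 0.072 and 0.085), and, for Mef2d and Mef2a, without lnc-31 siRNA 1 (0.094 and 0.072). Without lnc-31 siRNA 2 they were lost for Mef2d and Myod1 (0.10 and 0.061). Adjusted over the list alone, 4 rose and 2 fell, and camera did not call the list (adjusted p = 0.23), while fry did (adjusted p = 0.031). With 1 library left out, 1 or 2 rose and none fell.

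Cell cycle genes were lower. Of 41 genes of DNA replication and G1/S, 24 fell and none rose (median log2 fold change -0.24), and of 39 genes of G2/M and mitosis, 25 fell and none rose (median -0.23). Cdc6, which licenses replication origins, went from 24.6 ± 0.0701 to 17.9 ± 0.281 FPKM, the histone mRNA binding protein Slbp from 72.4 ± 3.04 to 51.2 ± 1.87 and the kinetochore component Nuf2 from 50.7 ± 0.929 to 32.4 ± 0.977. Camera gave adjusted p = 1.44e-13 for the first list and 6.43e-15 for the second, and adjusted p = 0.44 for each with an estimated correlation. Adjusted over the list alone, 33 fell and 1 rose in the first and 32 fell in the second. With scrambled siRNA 1, scrambled siRNA 2, lnc-31 siRNA 1 or lnc-31 siRNA 2 left out, 3, 2, 6 and 8 of the first list fell and 1, 1, 5 and 3 of the second, while the medians stayed between -0.26 and -0.20. With a constant prior variance 15 of the second list fell, and under quantile normalization or median of ratios scaling 1 of the first rose.

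Among 17 cell cycle inhibitors and D cyclins, 7 rose and 3 fell. Gadd45a, a growth arrest gene, rose from 18.3 ± 0.990 to 35.3 ± 0.103 FPKM and the inhibitor Cdkn1c from 4.84 ± 0.242 to 9.61 ± 1.06, while cyclin D1 (Ccnd1) fell from 107.1 ± 0.558 to 75.7 ± 0.676. Camera did not call this list (adjusted p = 0.17), and 7 rose and 4 fell adjusted over the list alone. With each library left out in the same order, 3, 3, 5 and 5 rose and 1 fell.

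Genes of the unfolded protein and integrated stress response rose, 15 of 28 against 1 that fell (median log2 fold change 0.33). Trib3, a target of the stress factors ATF4 and CHOP, rose from 9.72 ± 0.928 to 23.9 ± 1.03 FPKM, Ddit3, which encodes CHOP, from 39.9 ± 1.07 to 75.6 ± 0.382, and Nupr1 from 37.1 ± 1.46 to 75.4 ± 1.75. Slc7a11, the cystine transporter, had a log2 fold change of 0.73 (adjusted p = 0.0055). Camera gave adjusted p = 5.51e-11, and adjusted p = 0.44 with an estimated correlation, and adjusted over the list alone 20 rose and 1 fell. With scrambled siRNA 1, scrambled siRNA 2, lnc-31 siRNA 1 or lnc-31 siRNA 2 left out, 11, 11, 14 and 12 rose and none fell. Of 25 p53 targets 8 rose and 3 fell (median 0.06, camera adjusted p = 0.030, and adjusted p = 0.56 with an estimated correlation; 8 and 4 adjusted over the list alone). Those that rose included Sesn2, which had a log2 fold change of 0.57 and is also a stress response gene. In the same order of libraries left out, 2, 2, 6 and 4 of the p53 targets rose and 0, 0, 0 and 1 fell. With a constant prior variance 1 p53 target and none of the stress response genes fell.

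Of 33 extracellular matrix genes 16 rose and 2 fell (median 0.17), with periostin (Postn) at 3.45 ± 0.254 and 7.85 ± 0.312 FPKM and decorin (Dcn) at 7.84 ± 0.650 and 13.9 ± 1.33. Of 21 targets of SRF and YAP, transcription regulators that answer to actin, 11 fell and 1 rose (median -0.22). Srf itself fell from 17.1 ± 0.5001 to 10.3 ± 0.794 FPKM, calponin (Cnn1) from 6.36 ± 0.142 to 3.84 ± 0.115 and Axl from 106.7 ± 0.174 to 78.8 ± 0.132. Camera gave adjusted p = 1.18e-06 for the matrix list and 5.23e-06 for the SRF and YAP list, and adjusted p = 0.44 for each with an estimated correlation. Adjusted over the list alone, 19 matrix genes rose and 3 fell, and 14 targets fell and 1 rose. With scrambled siRNA 1, scrambled siRNA 2, lnc-31 siRNA 1 or lnc-31 siRNA 2 left out, 2, 3, 3 and 4 matrix genes rose and 3, 3, 4 and 4 of the targets fell. With a constant prior variance 9 matrix genes rose and 1 fell, and 6 targets fell and none rose. Fibroblast and mesenchymal markers had a median of 0.13, with 2 of 8 higher, Pdgfrb and the matrix gene Dcn (3 adjusted over the list alone; camera adjusted p = 0.042, and adjusted p = 0.56 with an estimated correlation). That camera call was lost under quantile normalization (adjusted p = 0.061), with a mean of 5 FPKM or more (0.082), without scrambled siRNA 2 (0.086) and without lnc-31 siRNA 2 (0.066), and Pdgfrb (0.20) lost its own with any 1 library left out (0.098 to 0.14).

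Among 19 interferon response genes 1 rose, Lgals3bp (log2 fold change 0.90; 1 adjusted over the list alone), and the median was 0.02 (camera adjusted p = 0.83). Quantile normalization and median of ratios scaling each also called 1 lower.

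**Figure D2:**
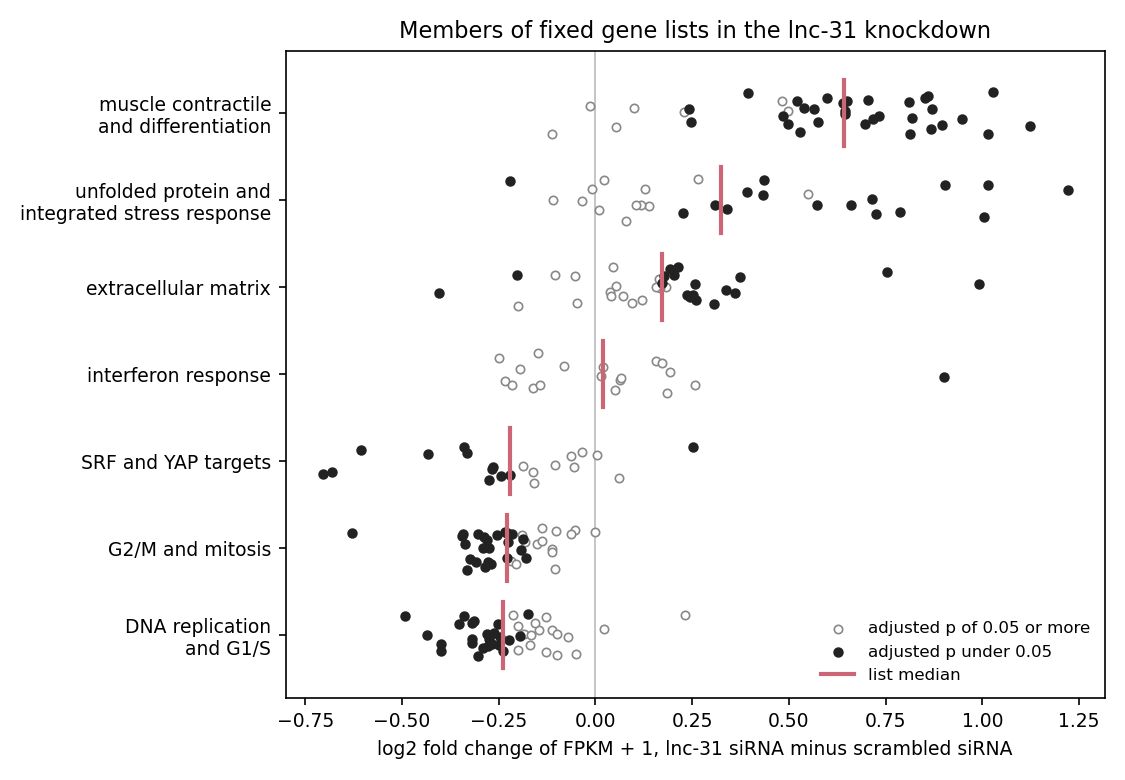
Log2 fold change of FPKM + 1, lnc-31 siRNA minus scrambled siRNA (horizontal axis), for the tested members of 7 gene lists, each member a point, filled where its adjusted p is under 0.05, with the list median as a red line. Muscle genes center at 0.64 and stress response genes at 0.33, cell cycle and SRF and YAP lists near -0.23, and interferon genes near 0.

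Cytosolic ribosomal protein genes had a median of -0.08 with 0 of 84 called by limma and 0 adjusted over the list alone (camera adjusted p = 0.00046, and adjusted p = 0.78 with an estimated correlation). Median of ratios scaling called 9 of the 84 lower. Quantile normalization called 1 lower and ended the camera call (adjusted p = 0.097). Cholesterol synthesis genes numbered 3 higher and 2 lower of 25 (median 0.02, camera adjusted p = 0.31; 6 and 2 adjusted over the list alone). Translation factors numbered 1 higher and 3 lower of 39 (median -0.01, 0.62), and oxidative phosphorylation genes 2 higher and 3 lower of 81 (median -0.04, 0.17), with the same counts adjusted over the list alone. Quantile normalization and median of ratios scaling each called 5 cholesterol synthesis genes and 4 translation factors higher and 5 oxidative phosphorylation genes lower. A constant prior called 1 cholesterol synthesis gene higher and 1 lower, and a mean of 5 FPKM or more left no oxidative phosphorylation gene higher, while without lnc-31 siRNA 2 camera called that list (adjusted p = 0.038). With 1 library left out, 0 or 1 gene of each of these lists was higher and 0 or 1 lower. Of 24 immediate early genes 4 rose and 4 fell (6 and 6 adjusted over the list alone; median -0.04, mean 0.02, camera direction down with adjusted p = 0.83). With any 1 library left out, 1 of them fell and 2 or 3 rose. Replication-dependent histones and mitochondrially encoded messages were included as signs of RNA quality. Histones, listed as a class of messages without a poly(A) tail, numbered 3 higher of 19 (median 0.11, camera adjusted p = 0.072, fry adjusted p = 0.045). Adjusted over the list alone, 3 rose. Those called included Hist1h1c and Hist1h2bc, and whether the called messages lack a tail was not checked. Without lnc-31 siRNA 1 the list median was 0.20. By limma, none of 9 mitochondrially encoded messages passed (median -0.16, camera adjusted p = 0.072; 0 adjusted over the list alone). Camera called the histones without scrambled siRNA 1 (adjusted p = 0.0047), without lnc-31 siRNA 2 (0.027) and, in an alternative chosen after seeing the data, without rows at an exact 0 (0.034). It called the mitochondrially encoded messages under median of ratios scaling (adjusted p = 0.0499), with a constant prior (0.038), without scrambled siRNA 1 (0.019) and without lnc-31 siRNA 1 (0.011). The row mt-Nd2, at 395110 FPKM in scrambled siRNA 2 and 3401 in scrambled siRNA 1, was itself called without scrambled siRNA 1 (log2 fold change -7.01, adjusted p = 0.0011). With mt-Nd2 taken out of the list, an alternative chosen after seeing the data, the list was not called without scrambled siRNA 1 (adjusted p = 0.11) or under median of ratios scaling (0.066), and was called with a constant prior (0.045) and without lnc-31 siRNA 1 (0.013). None passed of 5 osteoblast (median -0.08, adjusted p = 0.49; 1 lower under median of ratios scaling), 4 adipocyte (median 0.02), 3 neural or 2 epithelial, endothelial or blood markers (medians 0.01 and -0.05), although 1 neural marker was higher and 1 lower adjusted over the list alone.

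Over all genes, limma called 1429 of 11500 tested genes at an adjusted p under 0.05, 649 higher and 780 lower in the libraries labelled lnc-31 siRNA. The changes were small, with a median absolute log2 fold change of 0.33 among called genes, and 169 of them reached 1.5-fold (117 higher, 52 lower). Adm2, a peptide hormone, and Fgf21, a metabolic hormone, had log2 fold changes of 1.16 and 1.10, and their calls were lost without lnc-31 siRNA 2 (adjusted p = 0.064) and without scrambled siRNA 1 (0.057) respectively. The elastase Cela1 (1.07), Hfe2, which encodes the iron regulator hemojuvelin (1.03), the stress factor Atf3 (1.02) and the histone deacetylase Hdac11 (1.003) were among the 10 highest together with the stress and muscle genes above. Nomo1 fell from 28.4 ± 0.532 to 11.4 ± 0.396 FPKM and Pigs, a subunit of the GPI transamidase, from 30.4 ± 0.466 to 13.4 ± 0.707. Nptx1 (-1.32), the selenoprotein synthesis enzyme Sephs2 (-0.98), Lce1g (-0.98), the ubiquitin ligase Rnf11 (-0.97), the splicing factor Prpf18 (-0.97), the clathrin light chain Clta (-0.92) and protein kinase C beta (Prkcb, -0.91) were the other large falls. RP24-275B23.1 was at 3.71 and 3.49 FPKM with scrambled siRNA and is listed at 0 in both libraries labelled lnc-31 siRNA. The groups did not overlap in 60.2% of tested genes, against 33.3% by chance. The latter is an expectation only, since genes vary together across the 4 libraries. The share can therefore lie far from it without an effect of the siRNA, and it was not tested. The count of called genes was 289 without scrambled siRNA 1, 260 without scrambled siRNA 2, 491 without lnc-31 siRNA 1 and 415 without lnc-31 siRNA 2.

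The pull-down comparison asked which RNAs had peaks with lnc-31 probes and not with lacZ probes. With 1 library per probe set it has no replicate check and no test. The lnc-31 probes gave 596 peaks over 202.6 kb and the lacZ probes 476 peaks over 126.0 kb. Of the lnc-31 probe peaks, 54 (9.06%) overlapped a lacZ peak by 1 base or more and 542 did not. The widest peaks without lacZ overlap were 2600 bases each, in Cnot6l, a deadenylase subunit (chromosome 5, 96074401 to 96077000, mm10), and Nkap (chromosome X, 37147801 to 37150400). The others of the 10 widest lay in Sqle (2200 bases), Vegfd, Msl3 and Erlin1 (2000 each), Zmym5 and Atrx (1800 each), Zfp1 (1600) and Nbeal1 (1400). The widest lacZ peaks lay in Vim and Neat1 (1200 bases each), again in Neat1, and at 2 places in Ext1 (1000 each). The value read as the authors' p per peak, from its range alone, reached 2.05e-07 with the lnc-31 probes and 6.52e-05 with the lacZ probes.

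Rock1 (chromosome 18, 10064401 to 10182251, mm10) held 10 lnc-31 probe peaks and no lacZ peak. All were 200 bases wide. The lowest value read as p, 2.10e-05, belonged to the peak at 10181801 to 10182000, and 7 of the 10, at 0.0016 to 0.0084, lay above the median of the lnc-31 probe list (0.00059). Its paralog Rock2 held no lnc-31 probe peak and 3 lacZ peaks, and Ybx1 held no peak of either kind. At the locus of lnc-31 itself, the RefSeq noncoding gene Gm49890 (chromosome 4, 88909854 to 88942042) spans Mir31 and held 11 lnc-31 probe peaks and 6 lacZ peaks. Of the 11, 4 had no lacZ overlap, including the one over Mir31 at 88909801 to 88910800. The target locus was therefore not free of peaks in the lacZ background. Wherever peaks of both probe sets overlapped there, the value read as p was lower with the lnc-31 probes. It was 7.96e-07 to 0.000587 for the overlapping lnc-31 probe peaks and 0.000464 to 0.00407 for the lacZ peaks. The peak at 88927801 to 88928000, without lacZ overlap, had 5.39e-07. The median of the whole lacZ list was also higher (0.0010), and a difference between the probe sets at this locus was not tested.

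**Figure D3:**
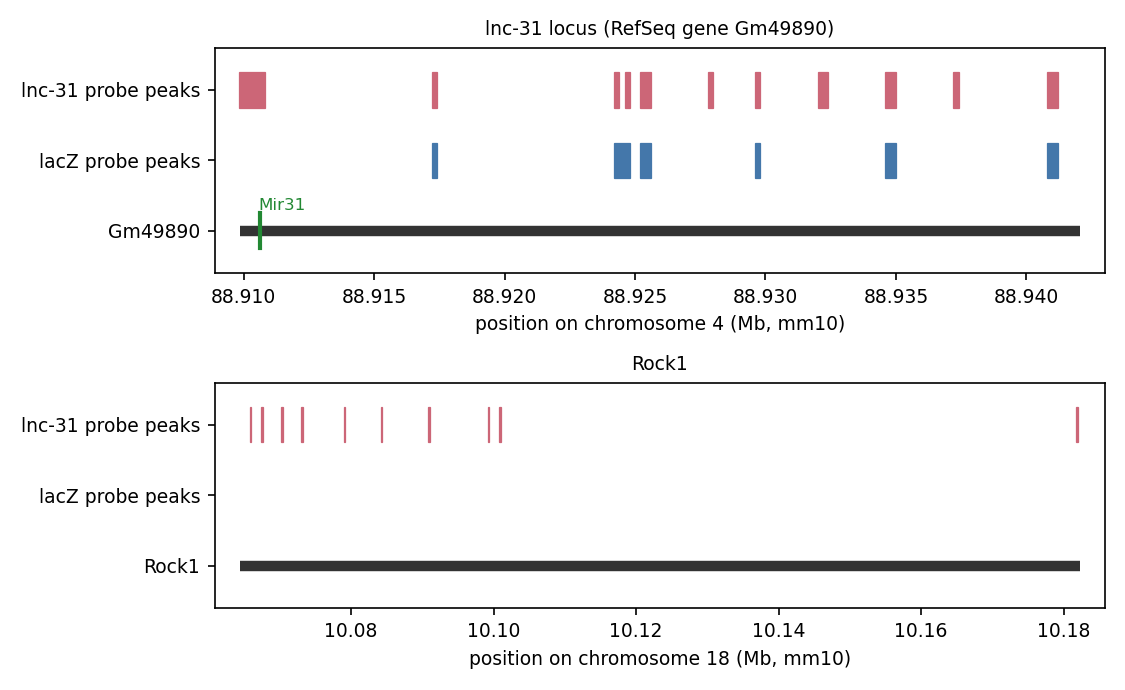
Positions in Mb (mm10) of peaks found with lnc-31 probes (red) and lacZ probes (blue) across Gm49890, the RefSeq gene at the lnc-31 locus with Mir31 marked in green, and across Rock1, with the span of each gene as a dark bar. Gm49890 has 11 lnc-31 probe peaks and 6 lacZ peaks, and Rock1 has 10 and 0.

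Peaks found only with the lnc-31 probes fell in 199 genes that had no lacZ peak, 183 of them protein coding. Of these genes 120 held 1 such peak and 49 held 3 or more, and the 10 genes with most held 155 peaks (28.6%). Atrx, a chromatin remodeler, held 30, Cenpe, a mitotic kinesin, 26, Nbeal1 24, Cnot6l and Arhgef10 13 each, Rock1 and Rreb1 10 each and Ccdc88a 9, and Spata7, Upf2 and Zmym5 tied at 8 for the last of these places. Peaks were assigned by overlap with the whole gene, so exons and introns were not told apart. The median log2(mean FPKM + 1) of the 183 tested genes in this set was 3.89, at percentile 33.0 among 10000 random lists of tested genes. Without the filter on low values it was at percentile 89.4. For the 215 tested genes with a lacZ peak the median was 5.29, at percentile 100. The median gene span was 39.8 kb for the first set and 88.7 kb for the lacZ set, against 22.8 kb for random lists of either size. A longer gene has more bases that a peak can overlap, so part of this excess over random lists is built in. The first set leaves out every gene with a lacZ peak, while the lacZ set keeps genes with peaks of both probe sets. The contrast in expression and span between the sets is therefore partly built in. The level of all genes with a lnc-31 probe peak was not computed.

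Genes with a peak found only with the lnc-31 probes were then looked up in the knockdown. The absence of a called lacZ peak does not show that their RNA was not recovered with lacZ probes. Of the 183 tested, 7 rose and 14 fell, and the median log2 fold change was -0.01. A difference of the set from other genes was not shown (limma's camera, adjusted p = 0.75 over 3 peak sets, and adjusted p = 0.92 with an estimated correlation). Fry found no common direction (adjusted p = 0.54). The share called was 11.5% in this set and 12.4% among all tested genes. Gadd45g rose from 43.4 ± 1.18 to 66.3 ± 3.40 FPKM. Eml1 fell from 51.0 ± 0.558 to 39.2 ± 1.11 and the histone chaperone Set from 304.4 ± 11.6 to 223.4 ± 9.91, and their calls were lost without scrambled siRNA 2 (adjusted p = 0.063 and 0.064) and, for Eml1, without scrambled siRNA 1 (0.057). Of the genes with most peaks, Arhgef10 (log2 fold change 0.33) and Ccdc88a (-0.33) passed. Arhgef10 lost its call without scrambled siRNA 1, scrambled siRNA 2 or lnc-31 siRNA 2 (adjusted p = 0.11, 0.11 and 0.10), and Ccdc88a with any 1 library left out (0.052 to 0.089). Of the 215 tested lacZ genes, 11 rose and 21 fell (14.9%), with a median of -0.01, and camera gave adjusted p = 0.75.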

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

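Alternatives without table rows at an exact 0, with the peaks of smaller p, with genes of 2 or more peaks, and with mt-Nd2 taken out of its list (9 lists called) were chosen after seeing the data. The 1429 called genes numbered 1080 to 1928 under other pseudocounts, filters, scalings and a constant prior, 169 with a fold of 1.5 or more, and 260 to 491 with 1 library left out, where fewer samples were fitted. Quantile normalization and median of ratios scaling moved the median of all tested genes to -0.00605 and -0.00252. Pairing by the labels' replicate numbers was not shown, as same-numbered deviations correlated at -0.09 over all tested genes. It is not excluded for single rows. With the replicate block 1613 genes and 10 lists were called, the added list being mitochondrially encoded messages. With that block 8 ribosomal protein genes, 1 osteoblast marker and 1 histone were called lower where the main fit called none. The row that names Mir31 had a limma adjusted p of 0.11 with the block, against 0.38 without it. Camera called 9 lists, 8 with a mean of 5 FPKM or more, 7 with quantile normalization (without ribosomal proteins and fibroblast markers), 10 with median of ratios scaling or a constant prior (with mitochondrially encoded messages), 8 to 11 with 1 library left out and 0 with an estimated correlation. The row that names Mir31, Rock1 and Ybx1 stayed short of the threshold under all alternatives run. With 1 library left out they stood at -0.25 to -0.04, 0.05 to 0.09 and -0.06 to -0.03. The set of genes with a peak found only with the lnc-31 probes also stayed short, at -0.03 to 0.01 with 1 library left out. The test direction of the interferon list turned under quantile normalization (median 0.0253), and its median ran from -0.0376 to 0.0438 with 1 library left out. With 1 library left out, turns of direction also occurred for immediate early genes (-0.0999 to 0.0184), Tubb3 (-0.0410 to 0.0624) and Lpl (-0.0125 to 0.160), none of them called; the cause was not tested. Of 448 comparisons of a named gene with 1 library left out, 341 kept side and direction, 102 lost the call in the same direction, 3 turned and 2 gained a call. Taking the wider peaks of each list gave 268 peaks and 119 genes found only with lnc-31 probes, and the peaks of smaller p gave 275 and 107, against 542 and 199, since fewer peaks entered. Other overlap rules gave 537 to 554 peaks. The exon overlap was not run, so the gene body alternatives equal the values reported, and ignoring strand changes nothing because 1 symbol fills that column. Depth is unknown and limits low rows in a way that cannot be quantified.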

Other observations

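Of 14 tested genes of the circadian clock, chosen after some of their values were seen, 7 passed the test, 1 higher and 6 lower. Clock, the transcription factor that drives the cycle with Arntl, fell from 22.9 ± 0.147 to 13.7 ± 0.378 FPKM (SD, n = 2 each; limma log2 fold change -0.70, adjusted p = 0.0044), and Nr1d1, a repressor of Arntl, from 19.5 ± 1.84 to 10.8 ± 0.104 (-0.79). Arntl rose from 4.59 ± 0.223 to 7.999 ± 0.0294 FPKM (0.69). Dbp (-0.81), Nr1d2 (-0.43), Tef (-0.44) and Per3 (-0.42) also passed the test, and Per1 (0.09), Per2 (-0.25), Cry1 (-0.07), Cry2 (-0.08), Bhlhe40 (-0.12), Bhlhe41 (-0.11) and Ciart (0.02) did not. With 1 library left out, Clock, Nr1d1 and Arntl kept their calls. Dbp lost its call without scrambled siRNA 2 or lnc-31 siRNA 1 (adjusted p = 0.076 and 0.059), Nr1d2 without scrambled siRNA 2 (0.056), Tef without either scrambled library (0.076 and 0.087) and Per3 with any 1 library left out (0.079 to 0.13).

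Genes with a lacZ peak included 6 of 33 tested extracellular matrix genes: Timp3, Col5a2, Lox, Vcan, Col1a2 and Col3a1. Independent lists would share 0.617 (Fisher's exact test, adjusted p = 0.00058), but genes with a lacZ peak were highly expressed and long. Random lists matched on expression and gene span shared 2.75 on average, and 4.46% of 10000 such lists shared as many, a comparison made after the overlap was seen and for this list alone. Ext1 held 48 lacZ peaks and 6 lnc-31 probe peaks, and Ebf1 18 and 0. Peaks of both probe sets fell on 39 FPKM rows, against 3.87 for independent lists, a value that takes no account of expression or length.

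All tests of explanations below were chosen after the results were seen. Muscle genes were higher and cell cycle genes lower in the libraries labelled lnc-31 siRNA. Median of ratios scaling applies 1 factor per library, and the median of all tested genes was already -0.0067. It could therefore hardly move these lists and does not test library scaling. Under quantile normalization the muscle median was 0.61 and the cell cycle medians were -0.23 and -0.21, which argues against library scaling. That 1 library was out of place is argued against by a muscle median of at least 0.59 with any library left out. An interferon response to the siRNA is argued against by an interferon median of 0.0204. Effects of the siRNA on other transcripts cannot be told apart from those of lnc-31, because the design has 1 siRNA treatment against lnc-31 and the row that names Mir31 moved by -0.14. The difference between siRNAs that the design names stays open as a biological explanation.

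The lower Clock and clock output genes may reflect another circadian phase at harvest. For Clock itself this is argued against by Clock (-0.70) and Arntl (0.69) moving apart, provided that a shift of phase would move them together. Whether they cycle together in these cells was not measured here. For the output genes a shift of phase stays open, since Arntl moved against Dbp and Nr1d1 as it needs. Less Clock is another candidate. Of 10 tested E-box targets other than Dbp and Nr1d1, 3 fell and none rose (camera p = 0.0069, and p = 0.29 with an estimated correlation). The estimate rests on 4 libraries and has little power, so less Clock stays undecided. The rise of Arntl does not separate it from a shift of phase, because lower Nr1d1, a repressor of Arntl, would go with higher Arntl under either. No harvest time is given in the labels.

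The row that names Mir31 did not fall past the threshold. A swap of 1 library of each group is argued against, since the other splits of the 4 libraries gave at most 1 called gene against 1429, although exchanged labels of whole groups would leave that count as it is. Too little precision to see a fall to 50% is argued against by the lower bound of the 95% interval, -0.39 on the log2 scale. Other transcripts counted in the row could hide a fall of lnc-31, as 2 names are merged in it, and nothing in the table separates them. No biological explanation was tested.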
